A study of Mus musculus with 6 samples.

How the data were processed

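Poly(A)-selected RNA-seq libraries were made from brain tissue of 6 male mice, which the labels call peri-hematomal in both groups, 3 mice with ICH and 3 sham. The labels' protocols name TRIzol extraction, a Bioanalyzer check and an Illumina TruSeq kit, and do not say whether the kit marked strand. The labels speak of randomly assigned mice, so the libraries of a group were taken as separate animals. Samples were grouped by their titles, and the replicate numbers come from the same titles.

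The authors deposited 1 table of 21871 rows by gene symbol and 6 columns. Its values are expected counts, as deposited by the authors, that is, reads assigned to genes and not normalized to library size. Per the submitters' processing notes, FastQC, HISAT2, featureCounts and DESeq2 were used, with no role or version, and the builds hg38 and mm10 are both named. Which tool made the fractional values is not given in the sources used here. In each library from 91.8% to 92.4% of the values were exactly whole, and the rest had decimals. Fractional counts can come from sharing a read among genes, so counts of paralogs and overlapping genes are uncertain. The 20 rows that repeat a symbol were summed with their namesakes, which gave 21851 symbols, and sums were rounded to whole numbers. No row was blank or a summary, and 0 columns belonged to samples outside the series.

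Gene positions are from GENCODE M21 (GRCm38, the same assembly as mm10), joined by symbol, which matched 19772 of the symbols (90.5%). The deposited table itself holds no coordinates. Of 168 named genes, 34 overlap another gene of the table on either strand.

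Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr, which left 14705, and libraries were scaled by TMM. The groups were compared by the quasi-likelihood F test (glmQLFit and glmQLFTest), two-sided, with Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 8115 genes. Standard errors were derived as the absolute log2 fold change divided by the square root of the F statistic. CPM values use the TMM-scaled library sizes, and log2 CPM has a prior count of 2. The median log2 fold change of all tested genes was 0.020, and other scalings moved it by less than 0.1, by -0.041 with DESeq2 size factors and 0.076 with upper-quartile factors. The share of higher genes among those called was 57.6%, 53.2% and 61.5% in the same order.

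Where a group had 1 to 3 counts of a gene, the ratio of pooled counts is given with its exact binomial 95% interval, and where it had 0, a bound against a floor of 3 counts over the group. Such intervals and floors cover counting error only. PCR copies are not independent molecules, and the table holds no molecular identifiers.

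Before the data were examined, 40 gene lists with 521 memberships were fixed, of which 520 had a row in the table. The rule for named genes was also fixed then. It takes Forl1 or Folr1. It also takes the 12 largest rises and the 12 largest falls among called genes with a mean of at least 2 CPM and groups that do not overlap, leaving out predicted genes. Lastly it takes up to 4 members of each list with the smallest p. Lists with at least 5 tested members, 38 of them, were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists. With the correlation estimated from the data no list was called, 1 list having an unadjusted p under 0.05. The self-contained test fry called 23 lists higher and 7 lower, against 24 and 7 by camera, but not the same lists. Called by camera and not by fry were glutamate and GABA receptors, cholesterol synthesis, oligodendrocytes and mitochondrially encoded genes. Called by fry and not by camera were immediate early genes and leptomeninges, both lower, and oxidative stress, higher. Lists not described in the results are given among the other observations.

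The edgeR step was tested on data simulated for this comparison over 14705 genes, 200 of them changed, of which 14594 passed the filter. It recovered 27% of the 100 genes changed by 1 on the log2 scale and 90% of the 100 changed by 2, and called 0.028% of unchanged genes. Simulated genes varied independently, so this says nothing of list tests on correlated genes. The data called 6707 genes, many more than the simulation changed, so the shares recovered may differ from those in the data.

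Alternatives were DESeq2 (1.42.0) size factors or upper-quartile factors in edgeR, the DESeq2 Wald test, limma-voom, no filter, a filter of 1 CPM in all 6 libraries, the replicate number as a block, removal of red cell, mitochondrial and choroid plexus genes, other list tests and leaving out each library in turn. A covariate for regional make-up, the mean log2 CPM of the striatal list minus that of the thalamic list, was added after seeing the data. It is made from the members of those lists, so their own results under it are fixed by its construction and not used here. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No other file was used.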

Results

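Brain tissue around an experimental hematoma was compared with tissue from sham-operated mice by RNA sequencing. Intracerebral hemorrhage (ICH), a bleed into the brain itself, had been induced in male mice by stereotactic injection, and the sham mice had surgery without a bleed. The labels describe 3 mice per group, randomly assigned, and each library was taken as 1 mouse. The agent injected, the time between surgery and collection, the brain region taken and whether sham tissue came from matching coordinates are not given in the sources used here. The study asked which transcripts change after ICH, with attention to those that fall. Its title names a gene written Forl1.

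Total counts were 15819383, 15921955 and 18816918 in ICH 1, 2 and 3 and 19837273, 17561585 and 18750876 in sham 1, 2 and 3. At these depths 3 counts in a library corresponded to between 0.146 and 0.204 CPM, the count scaled to a common library size. The first principal component of log2 CPM held 84.25% of the variance and separated the groups, with sham libraries between 71.6 and 91.3. ICH 1, 2 and 3 stood at -112, -89.7 and -48.8, so that ICH 3 lay nearest the sham libraries. Mitochondrially encoded genes took 9.35% ± 0.746 of the counts in sham and 12.9% ± 3.08 in ICH (SD, n = 3), with 16.3% in ICH 1.

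ICH tissue held more mRNA of macrophage, chemokine, reactive astrocyte and cell division genes. It held less mRNA of most choroid plexus genes and of part of the cortical and thalamic neuron genes. All 14 tested members of the infiltrating monocyte and macrophage list were higher, as were all 16 of the reactive astrocyte list. Of 20 choroid plexus epithelium genes, 18 were lower, as were 7 of 12 cortical and 6 of 10 thalamic neuron genes. By edgeR's quasi-likelihood test with a Benjamini-Hochberg adjusted p under 0.05, 6707 of 14705 tested genes (45.6%) differed, 3861 higher and 2846 lower in ICH. A change of at least 2-fold was found for 2534 higher and 1563 lower genes. In 9113 genes (62.0%) all ICH libraries lay on one side of all sham libraries, against 10% by chance. The number of changed genes was 4181 without ICH 2 and 4338 without sham 2, and the number of lower genes 1463 and 1705.

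No row of the table was named Forl1, and 1 row was named Folr1, which encodes folate receptor 1, a membrane protein that binds and takes up folate. Folr1 is a protein-coding gene on the minus strand of chromosome 7, from 101858331 to 101870788 in GRCm38 (mm10). Folr1 was close to undetected in ICH tissue, with 1, 1 and 0 counts in ICH 1, 2 and 3 against 107, 172 and 368 in sham 1, 2 and 3. Its mean fell from 11.4 ± 7.26 CPM in sham to 0.0431 ± 0.0375 CPM in ICH (SD, n = 3). The fitted log2 fold change was -7.90 with a standard error of 0.84 (edgeR quasi-likelihood test, adjusted p = 0.000632). Pooled counts were 279 times lower in ICH, with a 95% counting interval of 76.8 to 2306. Folr1 was not tested when at least 1 CPM was asked of all 6 libraries, because its ICH values lie below that. The span of Folr1 overlaps 7074 bp of Anapc15 on the opposite strand, which was higher in ICH (log2 fold change 0.55, adjusted p = 0.0474 by edgeR), and the strand setting of the counting is not given in the sources used here.

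Folr1 fell together with most other genes listed for the choroid plexus, the epithelium that secretes cerebrospinal fluid into the ventricles. Of the 20 tested genes of this list, which includes Folr1, 18 were lower and 1, the copper transporter Slc31a1 (log2 fold change 0.95), was higher, with the same counts adjusted over the list alone. The median log2 fold change was -3.28 (camera adjusted p = 8.49e-08, and adjusted p = 0.421 with an estimated correlation). Without Folr1, 17 of 19 genes were lower, with a median of -3.24 (camera p = 2.78e-08, and p = 0.124 with an estimated correlation). Ttr, which encodes the thyroid hormone carrier transthyretin and lies on chromosome 18 from 20665280 to 20674321, fell from 1764 ± 1120 CPM to 17.3 ± 4.33 CPM (log2 fold change -6.67, standard error 0.59, edgeR adjusted p = 0.000396). Sostdc1 and Otx2 fell by 6.77 and 3.31 on the log2 scale. Slc31a1, like F5 of the coagulation list and Anapc15, is named after its values were seen, and without sham 2 no gene of the list was higher by edgeR. Other lists also hold 2 of the 20 genes, F5 among the coagulation genes and Folr1 among the folate genes.

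The sham libraries differed from one another in these genes. Ttr was at 792, 1511 and 2990 CPM in sham 1, 2 and 3 and at 21.9, 16.7 and 13.3 CPM in ICH 1, 2 and 3. Folr1 kept a nearly fixed ratio to Ttr in sham tissue, with 6.58, 6.35 and 6.49 Folr1 counts per 1000 Ttr counts. In the pooled ICH libraries the ratio was 2.38 per 1000, from 2 Folr1 counts where the sham ratio gives 5.42. The ratio in ICH relative to sham was 0.369 with a 95% interval of 0.0445 to 1.34 (Fisher's exact test, two-sided, p = 0.189), so a difference in the ratio was not detectable at this depth.

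**Figure D1:**
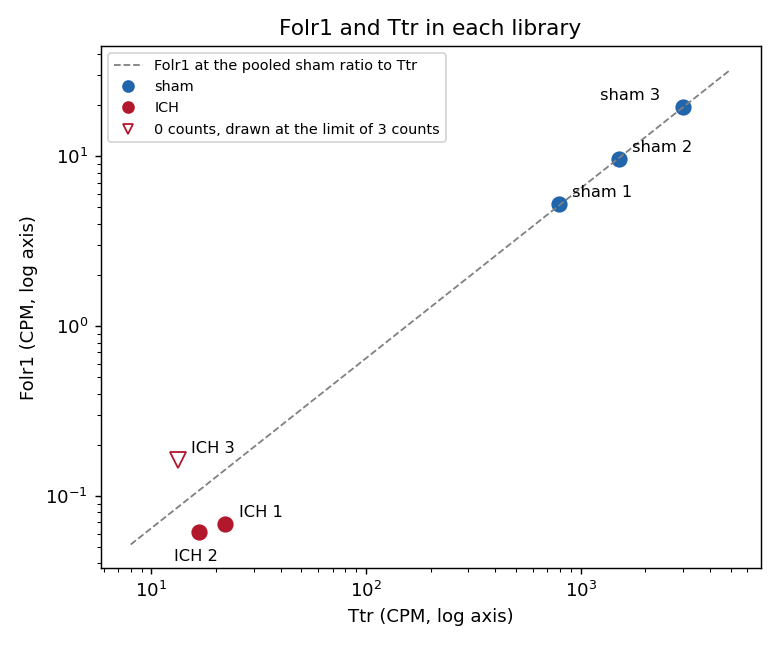
Folr1 against Ttr in each library, both in CPM on log axes. Filled circles are libraries with a Folr1 count, the open triangle is ICH 3 with 0 counts drawn at the value of 3 counts, and the dashed line is the pooled sham ratio of 6.47 Folr1 counts per 1000 Ttr counts. The 3 sham libraries lie along the line and the ICH libraries at its lower end.

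The 12 genes picked for the largest falls included Folr1, Kcnj13, Sostdc1, Ttr and Slc4a5 of the choroid plexus list. Kcnj13, a potassium channel, fell by 7.16 and Slc4a5, a sodium bicarbonate cotransporter, by 5.46 on the log2 scale. Mfrp fell by 5.55 and Myoc by 5.56. Prr32 was 76.4 times lower in pooled counts, with a 95% counting interval of 25.9 to 373. Neurod6 and Neurod2, transcription factors of cortical excitatory neurons, fell by 6.52 and 6.28, although neither was called by limma-voom (adjusted p = 0.152 and 0.104). Their sham libraries differed widely, with means of 32.03 ± 35.76 and 20.85 ± 18.44 CPM (SD, n = 3). Sham 3 stood at only 2.37 and 2.32 CPM, still above the ICH means of 0.335 and 0.258 CPM. The size of these 2 falls therefore rests mostly on sham 1 and sham 2. Calcr, the calcitonin receptor, fell by 6.04 and had a log2 fold change of -9.66 without ICH 3. Iqschfp had 0 counts in ICH and was at least 68.9-fold lower, with a floor of 3 counts over the group. It shares its span with Iqcj and Schip1, and Kcnj13, Mfrp and Myoc also overlap other genes of the table, so their counts are uncertain.

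Several of the 12 genes picked for the largest rises are known from macrophages and neutrophils. Arg1, an arginase of activated macrophages, rose from 0.454 ± 0.0424 to 272 ± 270 CPM (log2 fold change 9.21, standard error 0.98, edgeR adjusted p = 0.000636), with 581, 161 and 76.0 CPM in ICH 1, 2 and 3. The scavenger receptor gene Msr1 rose by 8.87, the transglutaminase gene Tgm1 by 8.87 and the apolipoprotein gene Apoc2 by 8.16 on the log2 scale. Cd5l rose by 8.36, the neutrophil collagenase gene Mmp8 by 8.09 and the metalloproteinase inhibitor gene Timp1 by 8.05. Pooled counts of the lectin gene Clec4d were 733 times higher (95% counting interval 203 to 6061) and those of the coagulation factor gene F7 were 296 times higher (81.5 to 2451). The ratios were 608 for Lilrb4b (208 to 2951), 722 for Sirpb1c (129 to 28570) and 655 for Cd244a (117 to 25910). Lilrb4b and Sirpb1c have close paralogs, Cd244a overlaps Ly9 and Timp1 lies within Syn1, so counts of these genes are uncertain.

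Immune genes rose across the lists that describe them. In the lists of infiltrating monocytes and macrophages and of chemokines and inflammatory cytokines, all 14 tested genes of each were higher, with median log2 fold changes of 5.38 and 5.07. Examples were the chemokine receptor gene Ccr2 (5.40) and the chemokine genes Ccl2 (7.20) and Cxcl10 (6.81). All 12 complement genes (median 3.36), all 14 interferon-stimulated genes (3.35) and all 12 antigen presentation genes (3.50) were higher, among them C3ar1 (5.38), Zbp1 (4.68) and Nlrc5 (3.51). The same counts were found adjusted over the list alone. Of the activated microglia and macrophage list 14 of 16 genes were higher, and 16 adjusted over the list alone, with Lgals3 at 6.56 and Cd68 at 4.74. Homeostatic microglia genes were higher in 10 of 11 cases, also adjusted over the list alone, with a median of 1.70 and Csf1r at 1.96. The camera adjusted p of these lists lay between 1.29e-07 for infiltrating monocytes and macrophages and 9.82e-06 for homeostatic microglia, and each of the 7 had an adjusted p = 0.421 with an estimated correlation.

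Rarer immune cells gave fewer testable genes. T and NK cell genes were higher in 9 of 12 cases and in 10 adjusted over the list alone (median 3.95, camera adjusted p = 0.000162, and adjusted p = 0.421 with an estimated correlation). Granzyme A (Gzma) was 127 times higher in pooled counts, with a 95% counting interval of 22.2 to 5044. Without ICH 3, 10 genes of that list were higher and 1 lower. Of the neutrophil list 7 of 9 genes were higher (median 3.25, camera adjusted p = 0.0179, and adjusted p = 0.446 with an estimated correlation). Adjusted over the list alone, 7 were higher and 1 lower, as was found over all genes without ICH 1. Of the border-associated macrophage list 6 of 9 were higher, also adjusted over the list alone (median 2.84, camera adjusted p = 0.00404, and adjusted p = 0.432 with an estimated correlation), with Folr2, another folate receptor, rising by 3.46. Other lists also hold 4 of these 9 genes, and 3 of the 14 infiltrating monocyte and macrophage genes, so these lists are not separate evidence. Only 3 B and plasma cell genes were tested, too few for a list test. Of these 2 were higher, 3 adjusted over the list alone, with a median of 2.94. The number was 1 without ICH 2 and 4 of 4 tested without ICH 1.

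Reactive astrocyte and cell division genes rose as well. All 16 reactive astrocyte genes were higher (median 4.04, camera adjusted p = 2.68e-08) and so were all 14 proliferation genes (median 4.94, camera adjusted p = 1.72e-08), with the same counts adjusted over the list alone. Both lists had an adjusted p = 0.421 with an estimated correlation. Which cells of the whole tissue made these transcripts was not tested. The intermediate filament gene Vim rose from 49.7 ± 14.5 to 1978 ± 793 CPM (log2 fold change 5.31, edgeR adjusted p = 0.000347). The hyaluronan receptor gene Cd44 rose by 4.45, and Rrm2, a subunit of ribonucleotide reductase, by 4.75. Homeostatic astrocyte genes did not move together, with 2 of 12 higher, 1 lower and a median of -0.089 (camera adjusted p = 0.511, and adjusted p = 0.827 with an estimated correlation), and the same counts adjusted over the list alone. The median was 0.14 without ICH 1. The lower number was 0 without ICH 1, ICH 2, sham 1 or sham 2 and 4 without ICH 3. Aqp4, the water channel of astrocyte endfeet, was higher by 1.85 and Gjb6, a gap junction gene, lower by 0.73 on the log2 scale, the latter not called without ICH 1 (adjusted p = 0.0550), ICH 2 (0.0553), sham 1 (0.0631) or sham 2 (0.0618). With the striatal minus thalamic score as a covariate, chosen after the data were seen, Gjb6 was at -0.46 and not called (edgeR adjusted p = 0.139).

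Vessel and matrix genes were higher. All 14 endothelial and blood-brain barrier genes were higher, also adjusted over the list alone (median 1.19, camera adjusted p = 7.57e-05), with the tight junction gene Cldn5 at 2.44. Pericyte and smooth muscle genes were higher in 9 of 10 cases, also adjusted over the list alone (median 1.23, camera adjusted p = 0.000725). Fibroblast and matrix genes were higher in 12 of 14 cases, and in 14 adjusted over the list alone (median 3.01, camera adjusted p = 2.39e-05), with the collagen gene Col4a1 at 3.68 and fibronectin (Fn1) at 3.90. These 3 lists had an adjusted p = 0.432 with an estimated correlation. Coagulation and fibrinolysis genes were higher in 13 of 14 cases and lower in 1, F5, with the same counts adjusted over the list alone. Other lists hold 3 of its genes, F5 among the choroid plexus genes and Pf4 and F13a1 among those of macrophages. It had a median of 4.25 (camera adjusted p = 3.35e-05, and adjusted p = 0.421 with an estimated correlation).

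Genes that handle heme and iron rose. Hmox1, heme oxygenase 1, which breaks down heme and lies on chromosome 8 from 75093621 to 75100589, rose from 8.59 ± 2.21 to 1914 ± 1675 CPM (log2 fold change 7.80, standard error 0.79, edgeR adjusted p = 0.000554). Its ICH libraries stood at 3817, 1259 and 666 CPM. Of 16 heme and iron genes 13 were higher, also adjusted over the list alone (median 2.30, camera adjusted p = 8.84e-05, and adjusted p = 0.421 with an estimated correlation), with the iron exporter gene Slc40a1 at 2.58. Without ICH 3, 1 gene of this list was lower. Of 5 red blood cell genes 3 were higher, 5 adjusted over the list alone, with a median of 1.38 (camera adjusted p = 0.0861, and adjusted p = 0.501 with an estimated correlation). The number of higher red cell genes was 1 without ICH 1 or sham 1 and 0 without ICH 2, sham 2 or sham 3, and the list was called without ICH 3 (camera adjusted p = 0.0172). Its median was 0.88 without ICH 1. The hemoglobin genes of the list are near-identical pairs whose counts are uncertain.

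Most pan-neuronal genes and part of the cortical and thalamic genes were lower. Of 12 pan-neuronal genes 11 were lower, 12 adjusted over the list alone, with a median of -1.21 (camera adjusted p = 0.000148, and adjusted p = 0.432 with an estimated correlation). Stmn2 fell from 289 ± 66.2 to 124 ± 6.09 CPM (log2 fold change -1.22, edgeR adjusted p = 0.0033). The number of lower pan-neuronal genes was 2 without ICH 2 or sham 2 and 6 without sham 1. Cortical excitatory neuron genes were lower in 7 of 12 cases, with a median of -2.01 (camera adjusted p = 0.000463, and adjusted p = 0.432 with an estimated correlation), and Tbr1 fell by 3.43. Thalamic neuron genes were lower in 6 of 10 cases, with a median of -2.21 (camera adjusted p = 0.00344, and adjusted p = 0.441 with an estimated correlation), and Calb2, calretinin, fell by 4.92. Tcf7l2 (log2 fold change -2.66) stood at 22.3 CPM in sham 3, near the 21.7 CPM of ICH 3. Slc17a6 stood at 42.8 CPM in sham 3 and 23.6 CPM in ICH 3. Sham 3 stayed well above ICH 3 in Calb2 (90.3 against 4.83 CPM) and Zic1 (134 against 34.1 CPM). The thalamic number was 3 without ICH 1 or ICH 2 and 10 without sham 3. Cortical and thalamic counts were the same adjusted over the list alone.

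Of 16 striatal projection neuron genes 0 passed the edgeR threshold, 0 adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. Their median was -0.42 (camera adjusted p = 0.226, and adjusted p = 0.771 with an estimated correlation), and it was 0.28 without sham 3, -0.093 without ICH 1, -0.22 without ICH 2, -0.71 without sham 1 and -0.70 without sham 2. Without ICH 3, 4 were lower, the median was -1.11 and the list was called (camera adjusted p = 0.0244). The mean log2 CPM of the striatal genes minus that of the thalamic genes was -0.22, 0.43 and 3.53 in sham 1, 2 and 3 and 2.55, 3.32 and 3.45 in ICH 1, 2 and 3, so that sham 3 lay with the ICH libraries. The mean of the cortical and thalamic scores minus the striatal score was -2.14 ± 1.73 in sham and -3.99 ± 0.398 in ICH (SD, n = 3). An exact permutation test, two-sided, gave p = 0.3, and since 3 against 3 cannot give less than 0.1, it could not have shown a difference at 0.05.

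**Figure D2:**
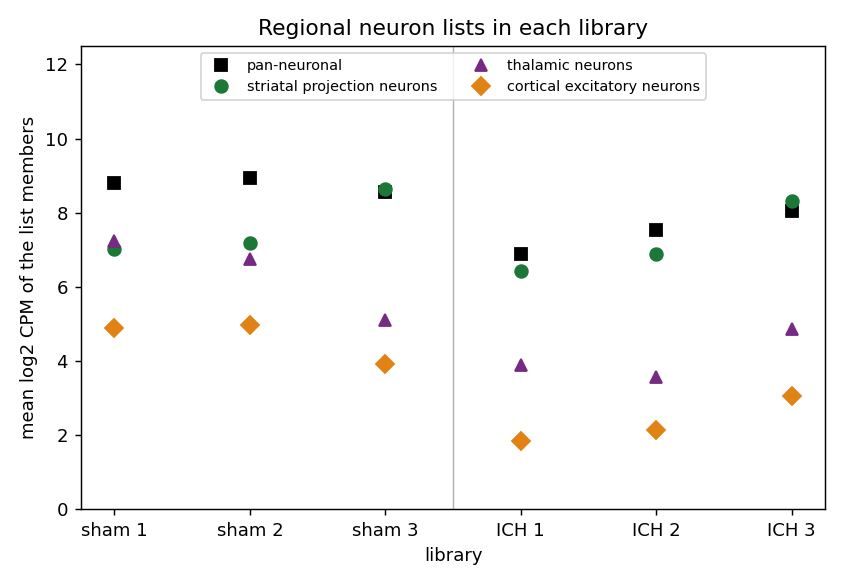
Mean log2 CPM of the members of 4 neuronal lists in each library, with 1 symbol per list and a vertical line between the sham and ICH libraries. Sham 3 has a thalamic score of 5.11, below those of sham 1 (7.25) and sham 2 (6.75).

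Of 14 glutamate and GABA receptor and scaffold genes 9 were lower, 10 adjusted over the list alone, with a median of -1.15 (camera adjusted p = 0.000167, and adjusted p = 0.441 with an estimated correlation), and Gria1 fell by 1.46. The number was 1 without ICH 2, 3 without sham 2, 5 without sham 3 and 14, with a median of -1.73, without ICH 3. Of 10 inhibitory interneuron genes 2 were lower and 1 higher, also adjusted over the list alone (median -0.74, camera adjusted p = 0.0845, and adjusted p = 0.454 with an estimated correlation). Vip fell by 1.96. The lower number was 1 without ICH 2, 5 without ICH 3 and 3 without sham 1, and the higher number was 0 without ICH 2, sham 1 or sham 2. The interneuron list was called with the striatal minus thalamic score as a covariate (camera adjusted p = 0.0383), and its median was -0.48 without sham 3. Immediate early genes, which respond to activity, were lower in 5 of 12 cases and higher in 2, also adjusted over the list alone (median -0.95, camera adjusted p = 0.0914, and adjusted p = 0.432 with an estimated correlation). Nr4a1 fell by 1.59 and Egr2 by 1.86. The lower number was 3 without ICH 2. The higher number was 1 without ICH 1, ICH 2, sham 1 or sham 3 and 0 without sham 2.

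Each called folate gene other than Folr1 was higher. Of 18 folate transport and one-carbon genes 10 were higher and 1, Folr1, was lower. Other lists hold 3 of the 18. Adjusted over the list alone 12 were higher and 1 lower (median 0.81, camera adjusted p = 0.00451, and adjusted p = 0.421 with an estimated correlation). The median was 0.53 without ICH 1. Tyms, thymidylate synthase, rose by 2.61 on the log2 scale. The reduced folate carrier gene Slc19a1 did not pass the threshold (0.14, edgeR adjusted p = 0.516), and it was chosen after its value was seen.

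**Figure D3:**
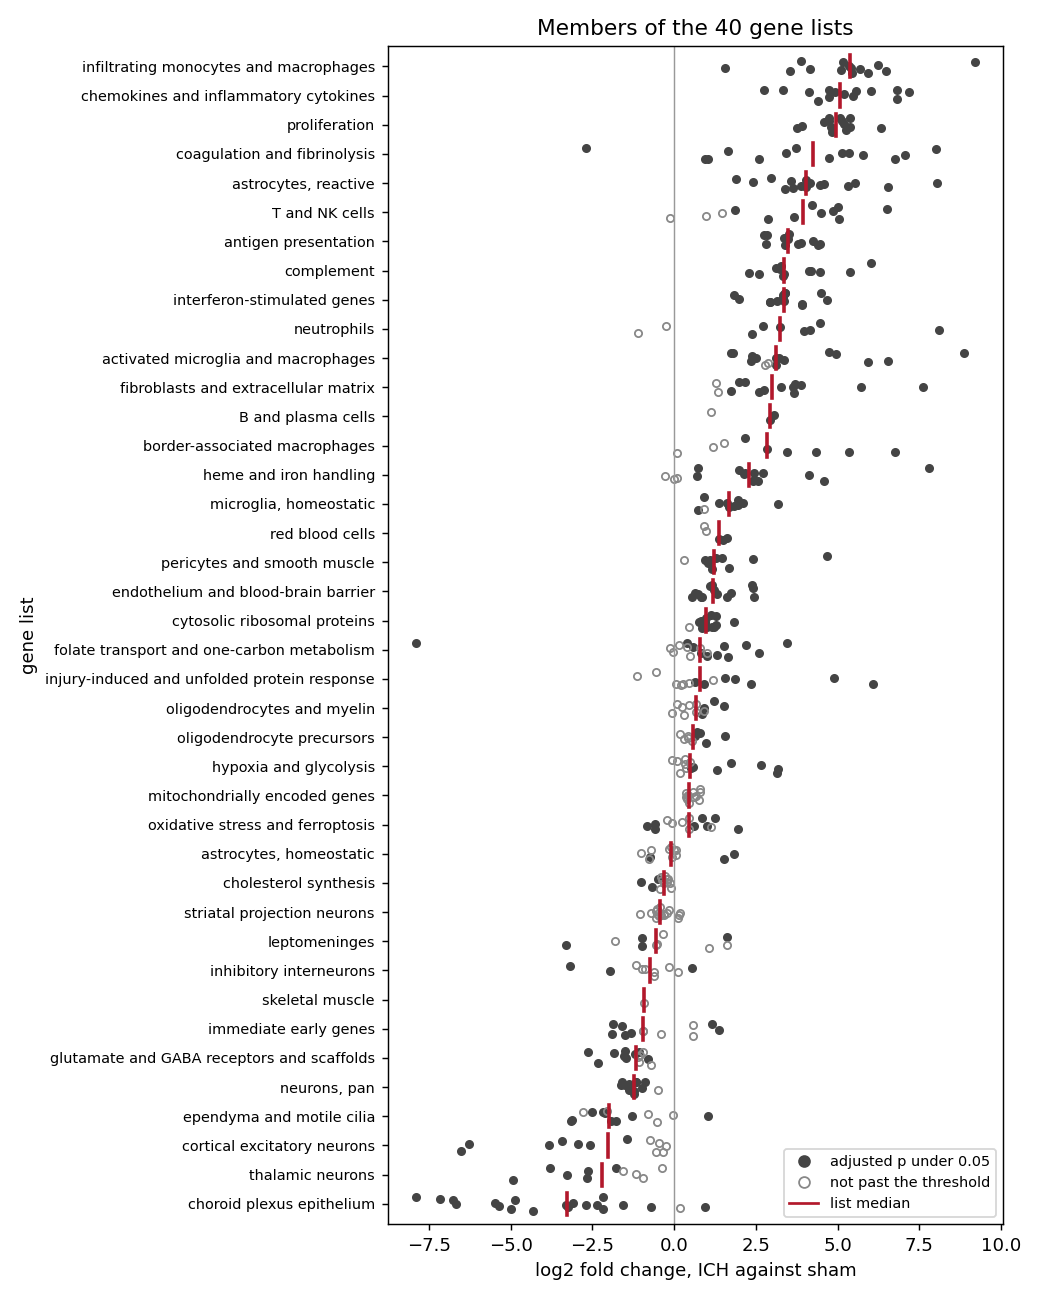
Log2 fold change, ICH against sham, of each tested member of the 40 gene lists. Filled points passed an adjusted p of 0.05, open points did not, and red bars mark list medians. The lists run from infiltrating monocytes and macrophages, with a median of 5.38, down to the choroid plexus epithelium, with a median of -3.28.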

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

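The covariate for regional make-up was chosen after the data were seen, and the other alternatives before. The fixed alternatives for normalized values do not apply, since the values are counts. Changed genes numbered from 5627 (1 CPM in all libraries) to 7565 (DESeq2 Wald test) with all libraries in, and from 4181 (without ICH 2) to 8160 (without ICH 3) when 1 was left out. Lower genes ranged from 1463 (without ICH 2) to 3852 (without ICH 3), with 1705 without sham 2. Every gene called both in the full data and under an alternative kept its direction. Folr1 had a log2 fold change from -8.54 (regional covariate) to -7.28 (limma-voom), with adjusted p from 2.13e-11 to 0.00607, and was not tested under a filter of 1 CPM or without choroid plexus genes. The choroid plexus list without Folr1 had medians from -3.53 to -2.10 and was called by camera with the preset correlation under each alternative that tested it, but not with an estimated correlation (p = 0.124). With an estimated correlation, camera called 0 lists higher and 0 lower, with adjusted p from 0.421 to 0.591 for the lists it otherwise called. For those lists the estimates ran from 0.048 (folate genes) to 0.92 (ribosomal proteins), against the preset 0.01. They were 0.51 for choroid plexus and 0.75 for proliferation genes. A larger correlation makes camera expect more variation of a list, which raises its p. What made the members vary together was not tested.

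Whether the replicate numbers pair the libraries is not settled. Deviations from the group means correlated by 0.21, 0.030 and 0.15 for numbers 1, 2 and 3. Across the groups sham 2 correlated best with ICH 3 (0.034), the other libraries with their own number. With the replicate number as a block, 7262 genes changed, 3969 higher and 3293 lower, and 25 lists were called higher and 9 lower, now with striatal neurons (camera adjusted p = 0.0120), interneurons (0.0315) and red cells (0.0490).

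Of the values of other named genes, 2314 kept their direction and side of the threshold, 86 lost the threshold, 33 gained it and 3 reversed. Reversed were Gpr6 (0.013), Tac1 (0.078) and Drd1 (0.22), none of them called, without sham 3. Leaving out 1 library, Gpr6 ranged from -1.75 to 0.013, Tac1 from -1.20 to 0.078 and Drd1 from -1.10 to 0.22. A filter of 1 CPM left fewer than 5 members in 5 lists that were otherwise called. Injury-induced genes (camera adjusted p = 0.0983) and ependymal genes (0.0701) were tested there and not called. With the regional covariate the cholesterol (0.211) and injury-induced (0.101) lists were not called and the interneuron list was (0.0383). Mitochondrially encoded genes were not called by limma-voom (0.0540).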

Other observations

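Of 14 ependyma and motile cilia genes, which line the ventricles, 8 were lower and 1 higher, 9 and 1 adjusted over the list alone (median -1.98, camera adjusted p = 0.000725, and adjusted p = 0.432 with an estimated correlation), with 3 lower without sham 3 and 4 lower and 0 higher without ICH 2. That list was not called with a filter of 1 CPM in all libraries (0.0701). Leptomeningeal genes were lower in 3 of 10 cases and higher in 1, also adjusted over the list alone (median -0.54, camera adjusted p = 0.201, and adjusted p = 0.446 with an estimated correlation), with 2 higher without ICH 3, 3 without sham 1 and a median of -0.85 without sham 2, and Slc13a4 fell by 3.32. Of 12 oligodendrocyte and myelin genes 4 were higher, also adjusted over the list alone (median 0.68, camera adjusted p = 0.0312, and adjusted p = 0.514 with an estimated correlation). The number was 2 without ICH 1 or sham 2 and 1 without ICH 2, sham 1 or sham 3, the median was 0.41 without sham 3, and the list was not called without ICH 2 (0.0565) or sham 3 (0.112). Oligodendrocyte precursor genes were higher in 5 of 10 cases, 6 adjusted over the list alone (median 0.59, camera adjusted p = 0.0214, and adjusted p = 0.432 with an estimated correlation). The number was 2 without ICH 2 and 3 without any 1 sham library, and the list was not called without sham 3 (0.0528). The 1 skeletal muscle gene tested, Acta1, did not pass the threshold (-0.92, edgeR adjusted p = 0.115) but did without ICH 3 (0.0381).

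Of 15 cytosolic ribosomal protein genes 14 were higher, 15 adjusted over the list alone (median 0.99, camera adjusted p = 8.13e-05, and adjusted p = 0.441 with an estimated correlation), with 7 without sham 2 and 9 without sham 3. Hypoxia and glycolysis genes were higher in 7 of 14 cases, also adjusted over the list alone (median 0.50, camera adjusted p = 0.0170, and adjusted p = 0.454 with an estimated correlation), with 4 without sham 1 or sham 2, and the hexokinase gene Hk2 rose by 3.18. Injury-induced genes were higher in 7 of 14 cases, also adjusted over the list alone (median 0.78, camera adjusted p = 0.0337, and adjusted p = 0.446 with an estimated correlation), with Atf3 at 4.89. The number was 3 without ICH 2 or sham 2, and the list was not called without ICH 1 (0.0580), ICH 2 (0.0634) or sham 1 (0.0505), with a filter of 1 CPM (0.0983) or with a covariate for regional make-up (0.101). Oxidative stress and ferroptosis genes were higher in 5 and lower in 3 of 14 cases, 6 and 3 adjusted over the list alone (median 0.46, camera adjusted p = 0.284, and adjusted p = 0.514 with an estimated correlation), with Nfe2l2 rising by 1.95, and the lower number was 0 without ICH 2 or sham 2 and 1 without ICH 1, sham 1 or sham 3. The median was 0.28 without ICH 1. Cholesterol synthesis genes were lower in 3 of 13 cases, 1 adjusted over the list alone (median -0.32, camera adjusted p = 0.0170, and adjusted p = 0.459 with an estimated correlation). The number was 1 without ICH 1, ICH 2, sham 1 or sham 2 and 5, with a median of -0.51, without sham 3, and the list was not called without ICH 3 (0.0746) or with the regional covariate (0.211). Of 13 mitochondrially encoded genes 0 passed the edgeR threshold, 0 adjusted over the list alone, 4 at an unadjusted p under 0.05, 4 by DESeq2 and 2 by limma-voom, with a median of 0.47 (camera adjusted p = 0.0483, and adjusted p = 0.591 with an estimated correlation). That list was not called without ICH 1 (0.124), ICH 3 (0.0751), sham 1 (0.0699), sham 2 (0.0681) or sham 3 (0.0868) or by limma-voom (0.0540), and 2 of its genes were higher without ICH 3. Its median was 0.23 without ICH 1.

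Of the tests that follow, those of the Folr1 to Ttr ratio, of Folr1 alone, of expression per cell, of both regional explanations and of both immune explanations were chosen after the result was seen. Those of genes that follow Ttr and of other splits were chosen before. The fall of Folr1 may reflect less choroid plexus in the ICH samples. A change in Folr1 alone is argued against by the 17 other list members that fell. Less choroid plexus tissue stays open, with a Folr1 to Ttr ratio of 0.369 in ICH relative to sham. The sham libraries were uneven, with Ttr at 792, 1511 and 2990 CPM in sham 1, 2 and 3. The mean log2 CPM of the choroid plexus list was 3.70, 4.36 and 5.13 in the same order. In ICH 1, 2 and 3 it was 1.20, 1.12 and 0.83, so the spread among sham libraries did not reach the ICH values. Whether uneven sampling extended to the ICH group was not tested and stays open. Outside the list, 54 genes that varied among the sham libraries as Ttr did had a median log2 fold change of -1.53. That lay below all of 10000 random lists of like mean sham expression. This test cannot decide, since the genes were picked from sham values that enter their folds, and sham spread was not matched. The genes also include Homer1 of the receptor and scaffold list and Lhx6 of the interneuron list, neither of them called. Past the threshold 26 of the 54 were lower and 1 higher, with Baiap3 at -4.55, Magel2 at -3.35 and Cartpt at -3.34. The tissue or region these genes come from was not tested, so their median need not be that of choroid plexus. Relative to Ttr the markers did not fall evenly: of 19, 0 had a ratio below that in sham beyond counting error and 16 lay above it, which loss of tissue alone would give only where other cells also express those genes, and this was not tested. Lower expression per choroid plexus cell cannot be told apart from these, since a larger fall of Ttr than of other markers also puts ratios above sham, so the value of 0 does not exclude it.

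Past the threshold, 7 of 12 cortical and 6 of 10 thalamic neuron genes were lower in ICH, and 0 of 16 striatal genes. The contrast may reflect a different mix of brain regions in the samples. The striatal minus thalamic score ranged over 3.75 among the sham libraries, against 0.36 for the pan-neuronal genes, so tissue of different regions within 1 group stays open. An even loss of neurons cannot be told apart from this, since the difference between the groups was -1.85 with an interval of 2 standard errors from -3.90 to 0.20. A loss of particular neurons after ICH was not tested and stays open.

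The higher immune genes may reflect immune cells in the tissue around the hematoma, a hypothesis. Fresh blood as the whole source stays open. The median of the monocyte and macrophage list exceeded that of the red cell list by 4.01 (95% bootstrap interval over genes 3.18 to 4.83). This cannot decide, since a fold depends on the level in sham. There the mean log2 CPM was 4.09 for red cell genes and 0.71 for monocyte and macrophage genes. A lower share of neurons raising all other types alike is argued against by the difference of 5.47 from homeostatic astrocyte genes (4.61 to 6.17). Both intervals hold the libraries fixed, so they do not cover variation among mice, and near-identical hemoglobin genes were drawn as if separate. With 1 library left out, the monocyte and macrophage median stayed between 5.05 and 5.74. The red cell median stayed between 0.88 and 1.71 and the homeostatic astrocyte median between -0.22 and 0.14. Whether cells entered the tissue or resident cells changed was not tested and stays open.

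The 6 libraries form 10 splits of 3 and 3, too few for a share under 0.05. The real split gave 6707 changed, 3861 higher and 2846 lower genes and 4097 changed at least 2-fold. The highest of the others was 0 for each by edgeR, with at most 395 genes at an unadjusted p under 0.05. No other split gave as many called genes. Lists called higher numbered 24, the highest other being 23 in either direction, so only the real split gave as many. Lists called lower numbered 7. In the other splits at most 16 lists were lower on the side holding ICH 1. Taking the larger count of either direction, the highest other was 23, and all 10 splits, the real split included, gave as many as 7. Each other split mixes the groups unevenly, so its list calls can carry part of the group difference.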
